A study of Penaeus vannamei with 70 samples.

How the data were processed

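Hepatopancreas RNA from single Pacific white shrimp (Penaeus vannamei, also called Litopenaeus vannamei) was measured on 70 single-colour microarrays, 1 shrimp per array. The arrays fall into 14 groups of 5 shrimp. Per the labels, each group is defined by strain (bred for resistance to Taura syndrome virus, or the susceptible Kona line), by the injected extract and by the day of sampling. The extracts came from shrimp free of specified pathogens (control), from shrimp infected with Taura syndrome virus (TSV) and from shrimp infected with yellow head virus (YHV). The injected volume was 60 µL per the labels' protocols, whereas the design text gives the same figure in millilitres. The protocols call the control extract one from saline-injected shrimp and the design text one from pathogen-free shrimp. The log10 dilution was -4 for the control and YHV extracts and -5 for the TSV extract. Day 0 shrimp were taken before injection according to the design text, although their labels carry the control extract.

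Per the labels' protocols, total RNA was treated with DNase on the column, amplified to amino allyl aRNA and coupled to Cy3. Each array carried 13056 spots, of which 1052 were markers, blanks or other control spots, and 580 of those were empty. The usual probe was printed on 4 spots and 34 probes on 8. Per the file headers, the deposited intensity of each spot is the linear QuantArray value from histogram quantification, without background subtraction and without crosstalk correction. The same files hold a local background value for each spot. The authors' processed table holds values for 4888 spots, which are 1222 probes, and they were treated as log2 values. How those values were made is not given in the sources used here. Set against the scanner values, each of the 70 columns matched its own array best, with a correlation of spot-centred values of at least 0.974, against at most 0.691 for any other array. The column medians lay between 10.28 and 10.48. The print row accounted for 87.2% of the variance of the per-spot offset between both sources, so the level of a spot in that table is not comparable between print rows. The direction was settled by this comparison. A correlation does not change with the log base, so neither the base nor the centring was settled by it. That table served as an alternative source of values.

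Background was corrected with normexp at an offset of 50, fitted on foreground and local background of all spots (limma 3.58.1, R 4.3.3). Control spots were then removed, the arrays were quantile normalized, and the log2 values of the spots of a probe were averaged. A further 204 spots that the export had marked to be ignored, on 3 arrays, were left out, which gave 14 probes a missing value on some array. A probe was kept when its mean intensity exceeded the 95th percentile of the empty spots on at least 5 of the 70 arrays. Of 2967 probes, 2360 were kept and 607 were not. At the scanner's ceiling of 65535 lay 144 spots of 9 probes, which were kept at that value.

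One limma model with a mean for each of the 14 groups was fitted to all 70 arrays, with 56 residual degrees of freedom, a prior of 4.98 degrees of freedom and moderated two-sided tests. Adjusted p-values are Benjamini-Hochberg values over the 2360 probes of a comparison, and a probe was called at an adjusted p under 0.05. The 17 comparisons were each virus against the control extract within strain and day, the difference of these changes between strains (resistant minus susceptible), the strain difference over the control groups, the control injection against day 0, and TSV against YHV averaged over both days. Design, alternatives and the rule for naming probes were set before the data were examined. The number of arrays limits the precision of every value.

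Spots are labelled with expressed sequence tag accessions and clone numbers (2792 probes) or with other labels (175 probes), and the files pair no probe with a gene. None of the accessions was found in the reference gene table used here (0 matches among 27905 genes, assembly ASM4276789v1). The 23 gene lists drawn up beforehand (immune effectors, heat shock, digestive enzymes, muscle, haemocytes and others) therefore matched no probe and none was tested. For the same reason probes are named by accession, at most 2 that rose and 2 that fell per comparison. The rule took the largest changes past the threshold, and for comparisons of 2 groups required at least 4 of the 5 arrays of each group on their own side of the midpoint of the group means. An accession can be shared by several probes, which was so for 5 accessions. Probes with different labels were not checked for a shared transcript. Some had levels close together across shrimp, as unknown1835 with CK572680 and CK571297 with unknown1429. Counts of probes are therefore not counts of transcripts.

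The folder of the scanned image split the arrays into 16 batches of 2 to 5 arrays, with at most 2 arrays of a group in any batch, and quantification ran on 10 days. Arrays of one image batch were alike: their deviations from the group means correlated by 0.234 on average, against -0.0115 for arrays of different batches. Of the first principal component, 15.7% of the variance, image batch explained 51.8% (adjusted R2) and group 33.4%; of the second, 12.8% of the variance, it explained 47.7% and group 35.2%. The model reported first has no batch term. Image batch and quantification day were each fitted as a block, and where a batch held arrays of both sides of a comparison, the differences within it were taken as well, a step chosen after the data were seen. Such batches had 1 or 2 arrays per side, too few for a test, and the probes counted were called on these same arrays. Organism numbers in the sample names are counters of different animals, since the tissue was dissected out, and were not used as pairs. No array duplicated another: the highest correlation between any pair of arrays was 0.982.

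A score per shrimp, devised after the data were seen, was the mean log2 level of 215 probes minus that of 190 probes. These were called higher and lower, respectively, in YHV day 2 than in day 0 shrimp on the average of both strains. They need not differ in each strain. Day 0 shrimp were uninjected, so this choice of probes also takes in injection and time. Differences in score were tested with exact two-sided permutation tests over the 252 relabellings of 5 against 5 shrimp, with Benjamini-Hochberg adjustment over 6 tests. The difference between strains in the TSV effect used 63504 relabellings of strain within TSV and within control shrimp. Correlations of fold changes across probes were set against 1000 draws of unchanged groups made from residuals of the real arrays, with or without a shared control group. Their simulation p is the share of draws at least as far from the draws' mean, the observed value included. Arrays were drawn across groups and without regard to image batch. The model was tested on simulated data with 200 of 2346 probes changed in 5 runs for each comparison of virus against control.

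Alternatives covered the background correction (none, normexp at an offset of 16), the normalization (cyclic loess, median scaling), the filter, the variance model, array weights, the arrays in the fit, organism number, image batch and quantification day as blocks, the authors' values, and leaving out each array of the compared groups.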

Results

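The series asked how the hepatopancreas, the digestive gland of shrimp, responds to TSV or YHV in a strain bred for resistance to TSV and in a susceptible strain. Each of the 14 groups held 5 shrimp. Per the labels, shrimp weighed 2.4 ± 0.84 g in the resistant and 3.1 ± 0.86 g in the susceptible strain. Mortality by day 2 and by the end was 7.4% and 33.3% in resistant shrimp given TSV, against 34.6% and 88.5% in susceptible shrimp. After YHV it was 69.6% by day 2 in the resistant and 90.0% in the susceptible strain, and reached 100% in both. Of control-injected shrimp 0% died in the resistant and 6.7% in the susceptible strain. The arrays had a median spot intensity between 385 and 1020, a local background between 157 and 186, and an empty spot level between 358 and 800. Between 647 and 2149 probes per array (median 1698.5) lay above the empty spots.

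After YHV, the hepatopancreas of both strains differed from controls on day 2. Mortality by then was 69.6% in the resistant and 90.0% in the susceptible strain. The design does not separate a response to the virus from the state of dying animals. In resistant shrimp 131 probes were higher and 94 lower than after the control extract, 225 in all. CK591038 rose 12.4-fold, from a log2 level of 9.47 ± 0.58 (SD, n = 5) to 13.11 ± 1.20 (log2 fold change 3.64, SE 0.53, limma adjusted p = 1.58e-06), and unknown1835 rose 11.6-fold (log2 fold change 3.53, SE 0.58, adjusted p = 1.6e-05). CK571487 fell from 14.65 ± 0.66 in controls to 10.44 ± 1.62 (log2 fold change -4.20, SE 0.60, adjusted p = 1.35e-06). CK571561 went from 13.22 ± 0.70 to 9.46 ± 1.80 (log2 fold change -3.76, SE 0.67, adjusted p = 5.2e-05), and was above background on 4 of the 5 YHV arrays; it fell 13.6-fold here, 8.49-fold without background correction and 14.8-fold at an offset of 16. With image batch as a block 249 probes were called, 196 of them among the 225. Image batches with both groups were 2, each with 1 array per group; 219 of the 225 probes had the sign of the main change in one and 223 in the other, though the probes were chosen on these arrays among others. Scaling arrays to one median in place of quantile normalization turned the balance of directions, to 81 higher and 125 lower, and array weights gave 356 calls.

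In susceptible shrimp on day 2 after YHV, 127 probes were higher and 99 lower, 226 in all. CK591058 rose 14.2-fold to a log2 level of 10.90 ± 1.57 (n = 5); it was above background on 1 of the 5 control arrays, where its level was 7.07 ± 0.25 (log2 fold change 3.83, SE 0.47, adjusted p = 3.82e-08). CK572335 rose 12.5-fold (log2 fold change 3.65, SE 0.51, adjusted p = 6.42e-07) and was above background on 3 of the 5 control arrays. CK571630 fell from 10.72 ± 0.60 to 7.29 ± 0.23 (log2 fold change -3.43, SE 0.55, adjusted p = 8.97e-06) and was above background on 2 of the 5 YHV arrays. The size of these changes depended on the background setting: without background correction CK591058 rose 5.22-fold, CK572335 rose 6.08-fold and CK571630 fell 4.31-fold, and at an offset of 16 the changes were 19.2-fold, 14.6-fold and 13.8-fold. CK571561 fell here too, 7.92-fold (log2 fold change -2.98, SE 0.67, adjusted p = 0.00113), 5.12-fold without background correction and 8.57-fold at an offset of 16. With image batch as a block 208 probes were called, 153 of them among the 226, and in the 1 batch with both groups 219 of the 226 had the same sign. Median scaling gave 91 higher and 90 lower, the fit on the compared groups alone 129 calls and the authors' values 139. Leaving out replicate 5 of this YHV group, whose median correlation with the other arrays was 0.834, the lowest of the 70, left 122 calls.

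**Figure D1:**
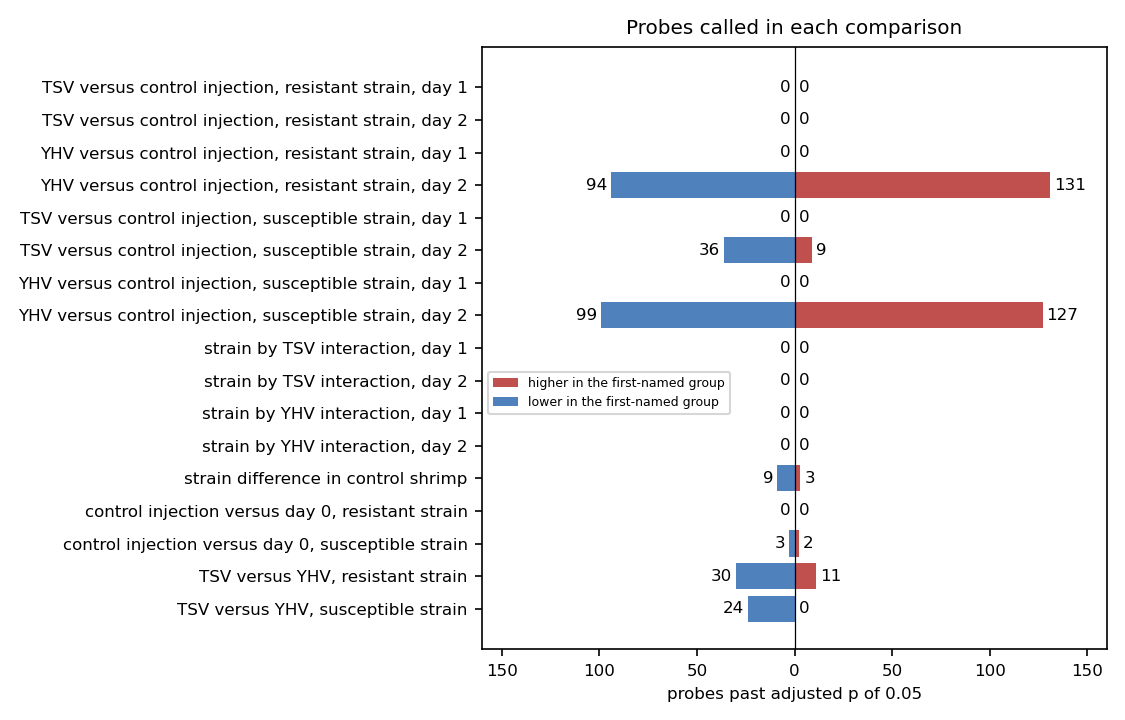
Number of probes (horizontal axis) with a limma adjusted p under 0.05 in each of the 17 comparisons (rows), drawn to the right where higher and to the left where lower in the first-named group; for the strain comparisons the direction is resistant minus susceptible. YHV on day 2 gave 225 calls in the resistant and 226 in the susceptible strain, TSV on day 2 gave 45 in the susceptible and 0 in the resistant strain.

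The YHV changes of day 2 ran in one direction in both strains. Of the probes called, 74 were higher and 46 lower in both strains, and 0 were called in opposite directions. Independent lists of these sizes would share 7.05 higher and 3.94 lower probes. Of the 225 probes called in resistant shrimp, 215 had the same sign in susceptible shrimp. Across 2346 probes, which are not independent replicates, the log2 fold changes of both strains correlated with r = 0.718 (rho = 0.544). Unchanged groups with separate controls gave 0.002 ± 0.186 (SD over draws), and at most 0.592 in 1000 draws (permutation p = 0.000999, the smallest these draws can give; 0.00999 after adjustment over 10 such pairs). The test of the difference between strains called 0 probes on day 2 (138 at an unadjusted p under 0.05 by limma, where 118 are given by chance) and 0 on day 1 (151 unadjusted).

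**Figure D2:**
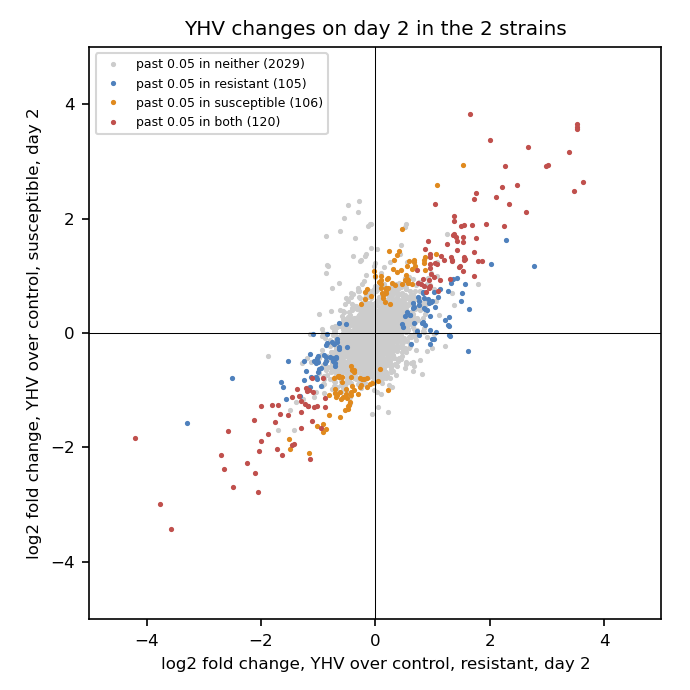
Each point is one of 2360 probes; the axes give the log2 fold change of YHV over control on day 2 in the resistant (horizontal) and the susceptible strain (vertical), coloured by the strain in which the limma adjusted p was under 0.05. The 120 probes called in both strains lie where both changes have one sign.

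On day 1, YHV gave no call in either strain: 0 probes in resistant shrimp (222 at an unadjusted p under 0.05 by limma, smallest adjusted p 0.0969) and 0 in susceptible shrimp (118 unadjusted). TSV gave 0 on day 1 as well, with 188 unadjusted in resistant and 152 in susceptible shrimp. The resistant TSV count on day 1 rose to 3, 6 and 1 without control replicate 1, control replicate 5 and TSV replicate 2 respectively, and the resistant YHV count to 1 without control replicate 1. In simulated data for the resistant YHV comparison of day 1, 98.4% of probes changed by 2 on the log2 scale were found, 63.2% of those changed by 1 and 13.2% of those changed by 0.5. With 200 of 2346 probes changed per run, these shares do not hold for a comparison in which few probes change.

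TSV gave calls in the susceptible strain on day 2. There 9 probes were higher and 36 lower, 45 in all. The TSV extract was more dilute than the control extract (log10 dilution -5 against -4), and the comparison does not separate the virus from that difference. CK571561, which also fell after YHV, went from 12.01 ± 1.45 to 8.81 ± 0.97 (SD, n = 5; log2 fold change -3.20, SE 0.67, adjusted p = 0.00627; 9.20-fold, 5.61-fold without background correction and 10.1-fold at an offset of 16), and BE188448 fell 4.29-fold to a level above background on 2 of 5 arrays (log2 fold change -2.10, SE 0.49, adjusted p = 0.0138; 2.33-fold without background correction and 5.08-fold at an offset of 16). CK570910 rose 4.07-fold (log2 fold change 2.02, SE 0.53, adjusted p = 0.0244) and BF023947 rose 2.84-fold and went from 10.12 ± 0.43 to 11.63 ± 0.99 (adjusted p = 0.0304). With image batch as a block 18 probes, 4 higher and 14 lower, were called, 12 of them among the 45, and neither CK570910 nor BF023947 was among them. In the 1 image batch with both groups (1 array each) 42 of the 45 had the same sign. Single shrimp moved the count: 6 without TSV replicate 4, 16 without TSV replicate 3, 87 without TSV replicate 2, 14 without control replicate 2 and 29 without control replicate 3. BE188448 was no longer called without control replicate 2 or TSV replicate 4. CK570910 and BF023947 were no longer called without control replicate 1, 2, 4 or 5 or TSV replicate 3 or 4, and BF023947 also not without TSV replicate 1. The count was 3, with 1 higher and 2 lower, in a fit on the arrays of these groups alone, 22 in the authors' values, 75 with median scaling and 95 with array weights. In the fit on these groups alone CK571561 had an adjusted p of 0.0878, the highest over all alternatives, the lowest being 0.00245.

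In resistant shrimp TSV gave 0 calls on day 2, with 73 at an unadjusted p under 0.05 by limma, fewer than the 118 given by chance, and a smallest adjusted p of 0.808. In simulated data for this comparison 99.2% of probes changed by 2 on the log2 scale and 72.0% of those changed by 1 were found. These runs had 200 of 2346 probes changed, by up to 3, so they do not give the share found where few probes change. The difference of the TSV changes between strains was not past the threshold for any probe: 0 on day 2 (176 unadjusted, smallest adjusted p 0.0506) and 0 on day 1 (131 unadjusted). On day 2 the count became 2 without susceptible TSV replicate 2, and 1 without susceptible TSV replicate 5, susceptible control replicate 4 or 5 or resistant control replicate 2. The 45 probes called in susceptible shrimp had the same sign in 38 cases in resistant shrimp. Across probes the TSV changes of day 2 correlated between strains with r = 0.152 (rho = 0.149), where unchanged groups gave 0.002 ± 0.186 (simulation p = 0.422, adjusted 0.603). With median scaling r was 0.408, where unchanged groups under that scaling, drawn after this value was seen, gave 0.006 ± 0.212 (permutation p = 0.0529).

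All 45 TSV calls of susceptible shrimp had the sign of the YHV change in the same strain, and 32 of them, 9 higher and 23 lower, were called for YHV too. With image batch as a block the shared calls were 14, and in the authors' values 15. Both comparisons use the same control shrimp, which alone gives them a common direction, and no count without change was computed for this overlap. The correlation of fold changes was 0.666, where unchanged groups sharing a control gave 0.492 ± 0.152 (simulation p = 0.256, adjusted 0.458). With the controls split between both comparisons it averaged 0.444, for which 0.492 is not the reference. Unchanged groups with separate, undivided controls gave 0.002 ± 0.186. No value for unchanged groups with split controls is given, so 0.444 was not tested. The covariance was 0.194 against 0.0543 simulated, a difference of 0.140, and 0.150 with split controls. Against the YHV changes of resistant shrimp, which share no array, 21 of the 45 were called in one direction, 6 higher and 15 lower, where 0.5 and 1.43 are given by independent lists. That pair of comparisons had r = 0.393 (simulation p = 0.034, adjusted 0.17). In resistant shrimp the covariance of TSV and YHV changes on day 2 was 0.0519 against 0.0543 simulated.

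Each shrimp was scored on the probes that distinguish YHV day 2 from day 0 shrimp. YHV day 2 shrimp, which define the score, averaged 0.88 ± 0.36 (n = 5) in the resistant and 0.77 ± 0.54 in the susceptible strain. Control shrimp of day 2 averaged -1.08 ± 0.18 and -1.02 ± 0.14. Susceptible TSV shrimp of day 2 were at -1.46, -1.21, -0.25, 0.06 and 0.23: 3 of the 5 lay above all 5 controls of their day, and the other 2 below all 5 (lowest control -1.206). The shrimp at -0.25 and 0.23 were on arrays of a set of 18 that share bright probes (described in the last section). The shrimp at 0.06 was not, nor were any of the 5 controls. The score has no term for this array set, so animal and array cannot be told apart there. The 5 TSV shrimp differed from controls by 0.494 on average (exact permutation p = 0.19, adjusted 0.38). Resistant TSV shrimp of day 2 averaged -1.04 ± 0.43, a difference of 0.040 (exact permutation p = 0.913), with 1 of 5 above all controls. The difference between strains in the TSV effect on the score was 0.454 (permutation p = 0.326, strain relabelled within each injection). These relabellings assume no strain difference in level or spread within either injection, so the p is not exact for that difference alone. Shrimp given YHV scored -1.12 ± 0.16 in the resistant and -0.79 ± 0.28 in the susceptible strain on day 1, with differences from controls of -0.227 (exact p = 0.167) and 0.099 (exact p = 0.508), and TSV shrimp of day 1 differed by -0.241 (exact p = 0.103) and -0.072 (exact p = 0.587). Of the 6 tests none passed after adjustment.

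**Figure D3:**
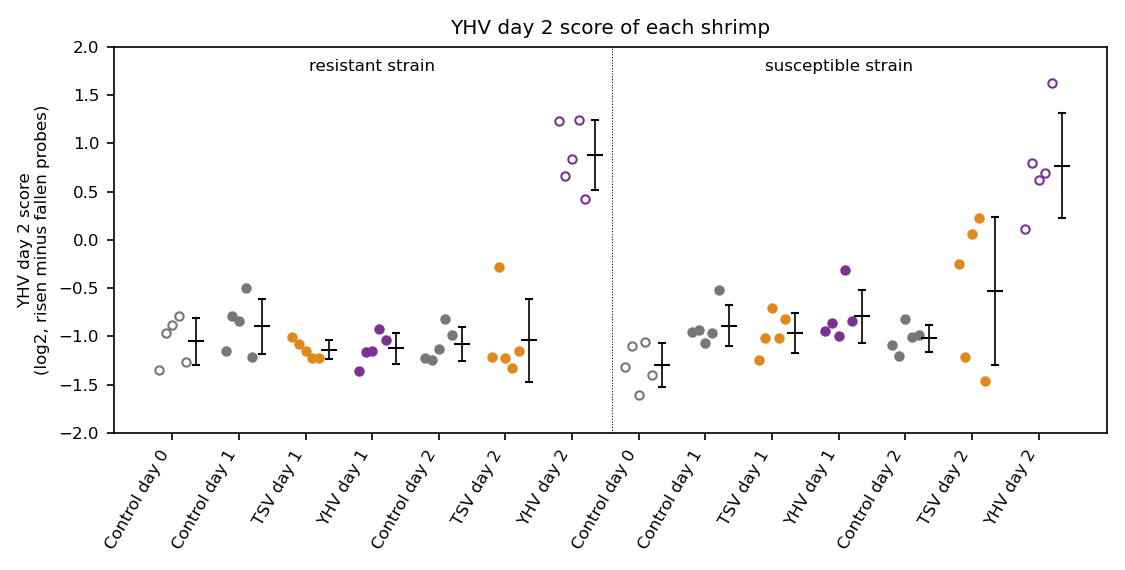
YHV day 2 score (vertical axis, log2 units: mean of 215 risen minus mean of 190 fallen probes) of each of the 70 shrimp by group (horizontal axis); points are shrimp, open where the group defines the score, and bars give mean ± SD of 5 shrimp. Scores of YHV day 2 shrimp lie above 0.11, and susceptible TSV shrimp of day 2 range from -1.46 to 0.23.

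Compared directly and averaged over both days, the viruses differed at 41 probes in resistant shrimp, 11 higher and 30 lower after TSV. The log10 dilution was -5 for the TSV and -4 for the YHV extract, so virus and dilution cannot be told apart. CK571384 was 3.56-fold higher after TSV, at 14.46 ± 0.46 against 12.63 ± 1.42 (pooled SD, 10 shrimp each; log2 fold change 1.83, SE 0.39, adjusted p = 0.00577), and CK571487 was 3.34-fold higher (log2 fold change 1.74, SE 0.42, adjusted p = 0.0123). Lower after TSV were unknown1835 (log2 fold change -2.03, SE 0.41, adjusted p = 0.00369) and CK572680 (log2 fold change -1.88, SE 0.45, adjusted p = 0.0102). These averages joined unlike days, as a split by day made after they were seen showed: on day 1 the log2 differences of these probes were 0.06 (SE 0.55), -0.27 (SE 0.60), -0.70 (SE 0.58) and -0.69 (SE 0.64), and on day 2 they were 3.60, 3.75, -3.35 and -3.06 with the same errors. CK571384 was at 14.52 ± 0.53 after TSV and 10.92 ± 1.93 after YHV on day 2 (n = 5 each). Calls numbered 41 with image batch as a block, 18 higher and 23 lower, 23 of them among the calls without it and CK572680 not, and 15 with quantification day as a block, 14 of them among those calls, without CK571384 and CK572680. Within 1 image batch on day 1 the sign of the average held at 30 of the 41, and within 1 on day 2 at 41. In susceptible shrimp 24 probes differed, all lower after TSV, among them unknown1835 (log2 fold change -1.87, SE 0.41, adjusted p = 0.00936) and CK572680 (log2 fold change -1.85, SE 0.45, adjusted p = 0.0187). Their differences were -0.84 (SE 0.58) and -1.22 (SE 0.64) on day 1, and -2.91 and -2.47 on day 2. With image batch or quantification day as a block limma called 0 probes there, while 22 of the 24 kept their sign within the 1 image batch with both viruses on a day. Under cyclic loess the split was 3 higher and 19 lower, and under median scaling 13 and 114. The fit on the compared groups alone gave 2 there. In resistant shrimp the count was 15 with median scaling, 117 with array weights, 82 without TSV day 2 replicate 2 or YHV day 2 replicate 5, and 27 without TSV day 2 replicate 5 or YHV day 2 replicate 1, and CK571487 was no longer called without the latter. In susceptible shrimp it was 37 without TSV day 1 replicate 3, 43 without TSV day 2 replicate 1, 10 without TSV day 2 replicate 5, 38 without YHV day 2 replicate 1 and 44 without YHV day 2 replicate 3. CK572680 was no longer called there without TSV day 1 replicate 4, TSV day 2 replicate 2 or TSV day 2 replicate 5.

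Among control shrimp the strains differed at 12 probes over the 3 sampling days, 3 higher and 9 lower in the resistant strain. CK571297 was 2.27-fold higher, at 8.76 ± 0.81 against 7.58 ± 0.53 (pooled SD, 15 shrimp each; log2 difference 1.18, SE 0.25, adjusted p = 0.0077), and unknown1429 was 2.26-fold higher (log2 difference 1.18, SE 0.27, adjusted p = 0.0181); each was above background on 13 resistant and 6 susceptible arrays. Without background correction both were 1.52-fold higher, and at an offset of 16 they were 2.57-fold and 2.58-fold higher. CK572618 was 3.67-fold lower in the resistant strain, at 9.82 ± 1.04 against 11.70 ± 0.49 (log2 difference -1.88, SE 0.32, adjusted p = 0.000405), and BF024091 was 3.14-fold lower (log2 difference -1.65, SE 0.32, adjusted p = 0.0018). All 12 had one sign on days 0, 1 and 2. Image batch as a block gave 6 calls, all among the 12 but without BF024091. In 5 pairings within an image batch and day, between 9 and 12 of the 12 had the same sign. Without resistant day 2 replicate 1 or replicate 3 there were 7 calls, and unknown1429 was not among them without the latter. Cyclic loess gave 3 higher and 18 lower, median scaling 4 and 4, array weights 24 calls and the authors' values 21.

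The 40 virus-injected shrimp are other animals, but shared the normalization, filter and variance estimate of that test. They showed the strain difference in the same direction at 11 of the 12 probes. All 11 passed there when adjusted over these 12 probes, and 10 passed over all 2360. CK572618 differed by -1.56 (SE 0.28) and CK571297 by 1.00 (SE 0.22). The exception was CK591050, with -0.78 (SE 0.20) in control and 0.08 (SE 0.17) in virus-injected shrimp. With control and virus arrays fitted apart, 12 probes were called in controls, 9 of them among the 12 above; 11 had the same direction in virus-injected shrimp and 9 passed there, adjusted over the list alone. Both probes that carry the accession CK572606 were among the 12, with log2 differences of -1.44 and -1.06 in controls. With image batch as a block 11 of the 12 had the same direction in virus-injected shrimp. Calls between control strains that also passed in virus-injected shrimp fell from 11 to 6 in that fit and to 5 with quantification day as a block, and rose to 23 with array weights.

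**Figure D4:**
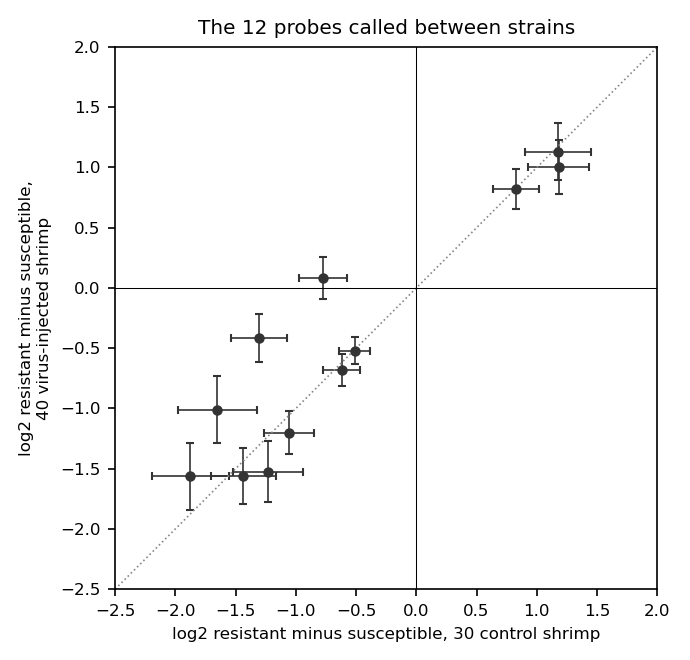
The 12 probes called between strains in control shrimp, with the log2 difference (resistant minus susceptible) in 30 control shrimp on the horizontal and in 40 virus-injected shrimp on the vertical axis; bars are standard errors and the dotted line marks equal differences. Of the 12 probes 11 lie on the same side of 0 in both.

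Shrimp given the control injection, sampled on days 1 and 2, were compared with uninjected day 0 shrimp. No uninjected shrimp were sampled on days 1 and 2, so injection and time cannot be told apart. In susceptible shrimp 2 probes were higher and 3 lower after injection. CK592760 rose 2.41-fold (log2 fold change 1.27, SE 0.26, adjusted p = 0.00517) and CK572420 rose 2.96-fold (log2 fold change 1.56, SE 0.37, adjusted p = 0.0338), while CV133215 fell 5.10-fold (log2 fold change -2.35, SE 0.48, adjusted p = 0.00517) and CK572707 fell from 12.90 ± 0.42 (n = 5) to 11.20 ± 0.50 (pooled SD, 10 shrimp; log2 fold change -1.70, SE 0.29, adjusted p = 0.000598). In resistant shrimp 0 probes were called (73 at an unadjusted p under 0.05 by limma), and 1 without day 1 replicate 2. The susceptible count was 20 with image batch as a block, 4 of the 5 among them and CV133215 not. With quantification day as a block it was 4, with 2 of the 5 among them and neither CK572420 nor CV133215. In each of the 2 image batches with both sides, all 5 had the same sign. A set of probes was bright on 18 arrays, among them 3 of the 5 day 0 arrays and 1 of the 10 injected ones; with this array set as a block 7 probes were called, 4 of the 5 among them. Array weights gave 28 calls, the authors' values 25, and no background correction 8. Under median scaling the count was 3, with 2 higher and 1 lower, and CK572707 was then no longer called. Leaving out single arrays gave 10, 2 and 1 (day 0 replicates 1, 3 and 4), 3, 14 and 3 (day 1 replicates 2, 3 and 5) and 3 and 9 (day 2 replicates 4 and 5). CV133215 was no longer called without day 0 replicate 3 or 4, CK592760 without day 0 replicate 4, and CK572420 without day 0 replicate 2, 3 or 4, day 1 replicate 2 or 5 or day 2 replicate 2 or 4.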

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

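The score was devised after the data were seen, and the measure of distance and the probes were set by fixed rules. These values were picked out by a fixed measure of distance: the gap of the most extreme of 5 shrimp to its nearest neighbour, divided by the range of the group, exceeded 0.71. Of 95 sets of 5 values tested, 7 had such a shrimp, where about 4.8 are given by chance (1 in 20). No difference between groups or strains was added by a test of the difference itself.

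Replicate 2 of the resistant TSV day 2 group stood apart on 3 of the values. Its YHV day 2 score was -0.278, against a median of -1.22 for the 4 other shrimp of its group. Its level of CK571487, a probe that fell after YHV, was 12.18 against 14.68. Its level of unknown1835, a probe that rose after YHV, was 11.35 against 9.92. These 3 values share probes and are not independent. No explanation was tested.

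Replicate 5 of the susceptible control day 1 group had a score of -0.524 against a median of -0.958 for the rest, and a log2 level of unknown1429 of 8.23 against 6.73. In the susceptible YHV day 1 group, replicate 4 had a score of -0.312 against -0.902, and replicate 3 had a log2 level of CK572680 of 9.65 against 10.99. Both arrays with an outlying score here came from one image batch and were bright for the probe set described in the last section. The control array was the only bright one of its group. In the YHV group replicate 5 was bright too, at a score of -0.84. Animal and array cannot be told apart for these scores.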

How the results depend on the processing

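The settings that used normexp against the empty spots, left out the 2 arrays least like the rest, or took the empty spot level or an array set (18 arrays that share a bright set of probes) into the model, or fitted control and virus arrays apart, were chosen after seeing the data, as were all settings for the score, the correlations and the shared counts. The cause of the changes below was not tested; fits on the compared groups alone or without 2 arrays hold fewer arrays by construction. The median of the spot pixels could not be tried, since the files give one summary per spot, and the gene list alternative was not run. Of the 26 named fold changes none reversed; 32 of their values under other settings and 30 without single arrays missed the threshold, none of them for the fold changes of YHV on day 2. Their size followed the background setting: without background correction all 26 were smaller and at an offset of 16 all 26 were larger, and all 26 stayed past the threshold in both. Every organism number marks a different animal. Deviations of arrays with one number in different groups correlated by 0.000366 on average (from -0.554 to 0.499), so they do not pair. With organism number as a block, TSV in susceptible shrimp on day 2 gave 45 calls, 44 of them among the 45 reported, and YHV on day 2 gave 222 in resistant and 227 in susceptible shrimp; the block moved no count by over 1.5 times.

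YHV on day 2 gave main counts of 225 (resistant) and 226 (susceptible), with 356 resistant calls under array weights, and 132 susceptible calls without the 2 arrays least like the rest, 129 on the compared groups alone and 139 in the authors' values. Leaving out single arrays gave 122 to 257 in the susceptible strain. The correlation of YHV changes between strains (0.718) lay between 0.659 (median scaling) and 0.768 (image batch as a block) in the settings run.

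TSV on day 2 in susceptible shrimp (45 calls) gave 95 with array weights, 75 with median scaling, 22 in the authors' values, 18 with image batch as a block, 3 on the compared groups alone, and 6 to 87 without single arrays. The 32 calls it shared with YHV became 14 with image batch as a block and 15 in the authors' values. The correlation of TSV changes between strains became 0.408 with median scaling.

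Counts of 0 became small counts. TSV in resistant shrimp gave 2 on day 1 with image batch as a block (0 to 6 without single arrays) and 2 on day 2 with array weights. YHV in resistant shrimp on day 1 gave 1 with array weights, with cyclic loess and without the 2 arrays least like the rest (0 to 1 without single arrays). The TSV interaction of day 2 gave 2 with array weights, and 1 with trend and robust, with image batch as a block and with normexp against the empty spots (0 to 2 without single arrays). The YHV interaction gave 2 on day 1 with array weights and 1 on day 2 on the compared groups alone. The control injection in resistant shrimp gave 3 with array weights, 2 with image batch as a block, and 1 with cyclic loess, quantification day or array set as a block, the empty spot covariate, or without the 2 arrays (0 to 1 without single arrays).

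The control injection in susceptible shrimp (5) gave 28 with array weights, 25 in the authors' values, 20 with image batch as a block, 10 with the empty spot covariate, 8 without background correction and 3 with median scaling. Without single arrays it gave 10, 2 and 1 (day 0 replicates 1, 3 and 4), 3, 14 and 3 (day 1 replicates 2, 3 and 5) and 3 and 9 (day 2 replicates 4 and 5).

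The strain difference of controls (12) gave 24 with array weights, 21 with cyclic loess and in the authors' values, 6 with image batch as a block, and 7 to 18 without single arrays. Those seen again in virus-injected shrimp (11) were 23, 20, 20 and 6 in these settings and 5 with quantification day as a block.

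TSV against YHV in resistant shrimp (41) gave 117 with array weights, 69 with array set as a block, 64 with the empty spot covariate, 15 with median scaling and with quantification day as a block. It gave 82 without TSV day 2 replicate 2 or YHV day 2 replicate 5, and 27 without TSV day 2 replicate 5 or YHV day 2 replicate 1. In susceptible shrimp (24) the counts were 127 with median scaling, 43 with array set as a block, 14 in the authors' values, 4 without the 2 arrays, 2 on the compared groups alone, and 0 with image batch or quantification day as a block. Leaving out TSV day 1 replicate 3, TSV day 2 replicates 1 and 5, and YHV day 2 replicates 1 and 3 gave 37, 43, 10, 38 and 44.

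Median scaling moved the median of all probes by over 0.1 in 8 comparisons, by up to -0.211 for TSV in susceptible shrimp on day 2, so directions are relative to that shift. Signal over background limits dim probes: 607 were not tested, and probes above the empty spots ranged from 647 to 2149 per array. In simulated data 23.8% of calls were false for susceptible YHV on day 1 and 8.03% for resistant TSV on day 1, both above the nominal rate. The other 6 comparisons of virus with control lay between 1.79% and 4.82%. Each rate comes from 5 runs. No spread between runs was set against these differences, so they are not read as properties of single comparisons.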

Other observations

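All tests in this part were chosen after the results were seen, except the counts over other splits, the counts of calls with image batch as a block and the test of the bright set against the empty spot level.

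Probes called in all 3 of the day 2 comparisons with calls (YHV in both strains, TSV in susceptible shrimp) numbered 20, of which 6 were higher and 14 lower. Among the 236 probes with the highest mean signal, 8 of those called for YHV were higher and 15 lower in resistant shrimp, against 123 and 79 among the other probes. The same split was 5 and 15 against 122 and 84 in susceptible shrimp. For TSV in susceptible shrimp on day 2 it was 0 and 3 against 9 and 33. These directions are those under quantile normalization, and median scaling turned the balance of the YHV calls in resistant shrimp. Over all 7 pairs of groups the strains differed at 103 probes, 47 higher and 56 lower in the resistant strain.

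BF024200 and CK571612, singled out after their values were seen, had a high and a low level with nothing between them. BF024200 was at 15.29 ± 0.34 in 53 shrimp and at 7.75 ± 0.70 in 17, and CK571612 was low in the same 17 shrimp (r = 0.992 over arrays), where the probes were above background on 9 and 1 arrays respectively. Of 35 shrimp per strain, 2 resistant and 15 susceptible were low, but the probes were noticed among the largest strain differences, so Fisher's exact p of 0.000528 by strain is no test. Failed spots are argued against by all 136 spots of both probes being low on those arrays, and image batch by 13 of the 16 batches holding both levels. A missing or divergent sequence in some shrimp may leave the probes unbound, which stays an untested hypothesis, as does a link with strain; no sequence was analysed here.

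A set of 22 probes that follow BE188592 (r over 0.8 across arrays) was bright on 18 arrays, where BE188592 had a median log2 level of 13.46, and dim on 52, with a median of 6.98. All arrays were bright in 4 image batches (17 arrays) and none in 11 (51 arrays), so that 15 of 16 batches held one level; no probe of the set was called in the 17 comparisons. A batch difference in printing or hybridization is a candidate source, consistent with 15 batches of one level. Array brightness stays open: 4 of the 52 dim arrays had empty spots above the median of the bright ones, past the bound of 3 set beforehand by less than the counting spread, while 17 of the 18 bright arrays lay above the dim median (medians 474 and 407). In a model with the groups, 884 of 2360 probes differed between these 18 arrays (6 resistant, 12 susceptible) and the rest; the susceptible day 0 group held 3 and its 10 injected controls 1, the susceptible TSV and YHV groups of day 2 held 2 each and their controls 0, and no biological explanation was tested.

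The YHV change of day 2 was weighed against both technical sources. Of 331 probes called in either strain, 254 (76.7%) stayed past the threshold in the same direction in at least 1 strain with image batch as a block. By strain, 196 of the 225 resistant and 153 of the 226 susceptible calls were called again. The median ratio of blocked to unblocked log2 fold changes was 0.990 in resistant and 0.929 in susceptible shrimp. With the empty spot level as a covariate 299 (90.3%) stayed in at least 1 strain. These values argue against either source as the whole cause of the pattern, which may reflect the infection; with mortality of 69.6% and 90.0% by day 2, a response to the virus and the state of dying animals were not separated by this design.

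Other splits of the same arrays were counted in 100 splits per comparison, the real one included. For YHV on day 2 in both strains, susceptible TSV on day 2 and the strain difference, 1 of 100 gave as many calls. This was the real split alone, the smallest count possible, and it was not adjusted over the comparisons. Arrays of one image batch are alike and the splits ignored batch, so they do not exclude a grouping by batch. With image batch as a block the calls were 249, 208, 18 and 6, with 196, 153, 12 and 6 among those without it. Without TSV replicate 4 the susceptible TSV count was 6. The real 225, 226, 45 and 12 stood against highest others of 119, 98, 36 and 2. The count was 2 of 100 for TSV against YHV in resistant shrimp (41 against a highest other of 53), 3 of 100 in susceptible shrimp (24 against 151) and 3 of 100 for the control injection in susceptible shrimp (5 against 14). These shares are under 0.05 but were not adjusted over the comparisons, and other splits exceeded the real one. For these 3 comparisons chance is therefore not excluded. Arrays of one image batch are alike, so a grouping by batch stays open as well. With image batch as a block 23 of the 41 and 4 of the 5 calls were made again, and 0 of the 24. For TSV against YHV in susceptible shrimp the other splits with as many calls, 151 and 57, each had 7 of the bright arrays on one side and 1 on the other, whereas the real split had 4 on each. Such counts point to a structure of the samples. The array set was not unevenly divided in every such split: the resistant split with 53 calls had 2 and 1 bright arrays, as the real one did, and the control injection splits with 14 and 12 calls had 2 and 2, and 3 and 1. In susceptible shrimp the real count was 43 with the array set as a block and 0 with image batch as a block. For the 10 comparisons in which limma called 0 probes (between 73 and 222 at an unadjusted p under 0.05), all 100 splits gave at least as many by construction, which says nothing about chance; the highest others ran from 1 to 23.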
